A study of Mus musculus with 6 samples.

How the data were processed

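Total RNA of mouse bone-marrow-derived macrophages was depleted of ribosomal RNA with biotinylated probes, fragmented by heat, reverse transcribed from random primers with actinomycin D and ligated to Illumina adapters, per the labels' protocols. There were 3 samples exposed to L-OHP and 3 given fucoidan before L-OHP, grouped by the treatment in the labels. Per the submitters' processing notes, HISAT2, StringTie, DESeq2, limma, bcl2fastq 2.0 and the genome build mm10 were used, without their roles or other versions, and the counting of reads, the use of strand and the annotation release are not given in the sources used here.

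A single table of 55401 Ensembl genes held all values. The authors' expression values were FPKM per gene and library, per the file headers, with 0.0001 in place of 0, which was set back to 0 here. The fold column was the authors' ratio of the mean FPKM of L-OHP+FUC to that of L-OHP, per the file headers and tested on the values, and the log2 column was the authors' log2 of that ratio. A p-value and a q-value per gene were deposited by the authors, per the file headers, and which tool gave them is not stated. The authors' mark of significance matched a p-value under 0.05 with a fold of at least 2 for every gene. The deposited FPKM hold no read counts. Where low genes with transcripts of at least 400 bases differed by whole-read steps, the step gave the implied depth, which was 15.7 to 18.6 M (mega) fragments per library. Only 37.6% to 43.2% of low values were whole within 0.03 reads, so no counts were recovered, no counting interval was computed and no count-based test was run. An exact 0 is given here as listed at 0, since a failed estimate cannot be told from absence.

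Because the table holds FPKM, limma 3.58.1 (R 4.3.3) was run on log2(FPKM + 1), with group as the only term, empirical Bayes moderation with an intensity trend, two-sided tests and Benjamini-Hochberg adjustment at 0.05. Genes with at least 0.5 FPKM in at least 3 of the 6 libraries were tested, 12084 in all. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes, and are L-OHP+FUC relative to L-OHP. Values per group are mean FPKM ± SD. Before averaging, the libraries were checked for identical values, and no pair shared more than 13 identical values among tested genes.

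Before the data were examined, 22 gene lists and 8 cell type marker lists were fixed, together with the tests, the alternative settings and the rule for named genes. Lists with at least 5 tested members, 26 in all, were tested with limma's camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation and fry beside it, adjusted over the lists. Camera compares a list with all other tested genes, so higher or lower by camera is relative to them. Where a symbol named more than 1 row, as 254 rows did, the gene with the higher mean FPKM was used. Named were the 8 highest and 8 lowest log2 fold changes among genes past the threshold whose groups did not overlap, with a mean of at least 1 FPKM in a group and no predicted name. The rule also covered the members with the smallest p in each list, up to 4 in a list past the threshold and up to 2 in others, and 17 genes chosen in advance. The text names only part of the list members so covered. The rule's exclusion of predicted names covered symbols ending in Rik, and 9930111J21Rik1 and 9930111J21Rik2 were eligible because theirs end in a digit. Coordinates, biotypes, GC content and the length of the longest transcript came from GENCODE M21 (GRCm38, the assembly of mm10), matched by gene ID for 99.5% of the rows, and 12074 of the 12084 tested genes had a GC content.

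The alternative settings fixed then were a pseudocount of 0.1, no filter, a mean of at least 5 FPKM, median ratio rescaling, quantile normalization, the replicate number as a block, moderation without the trend, thresholds of 0.1 and 0.01, a fold of at least 2, an estimated correlation, and leaving out each library in turn. Chosen after seeing the data were a correction for GC content and length, with and without the block, protein-coding genes only, leaving out both libraries with the steepest GC trend, and a camera test of the KEGG pathways in the deposited table with at least 15 tested genes. The correction subtracted from each library a loess trend (span 0.3, 4 robust iterations) of its deviations from the gene means, on GC content and then on log2 length. For comparison with gene lists of like composition, 10000 random lists were drawn in 10 classes of GC content, 3 of length and 5 of level.

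The tests were tried on simulated data with known answers, drawn for the 12084 genes of this comparison. Noise was drawn independently for each gene, without deviations shared within a library, and changed genes were taken only above a minimum level. The simulation therefore checks the code under these conditions and does not give the error rates in the real data. Of 67 genes changed 1.5-fold 27 were recovered, of 67 changed 2-fold 65, and of 66 changed 3-fold 63, with 11 false calls beside 200 changed genes and 0 calls when no gene was changed. A GC trend put into the simulated libraries gave a Spearman correlation of 0.79 with GC content before and 0.00041 after the correction. Such a drop was bound to follow from a fit on GC content itself, and the trend gave 1 call before and 2 after the correction. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.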

Results

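Gene expression was measured in mouse bone-marrow-derived macrophages, phagocytes grown in culture from marrow precursors, by sequencing of total RNA from which ribosomal RNA had been removed. After 7 days of culture, 3 samples (L-OHP) received 5 µM L-OHP, the usual abbreviation of the platinum chemotherapy drug oxaliplatin, for 12 h. The other 3 samples (L-OHP+FUC) were given fucoidan, a sulfated fucose-rich polysaccharide of brown algae, at 250 µg/ml for 12 h before the same L-OHP exposure. The comparison asks what fucoidan pretreatment did to the transcriptome of macrophages exposed to the drug. The series is concerned with neutrophil extracellular traps (NETs, webs of DNA and granule proteins released by neutrophils) and with the nerve damage that chemotherapy causes. Untreated macrophages and macrophages given fucoidan alone were not analysed here, so each difference is between drug-exposed cells with and without fucoidan.

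Values were FPKM for 55401 genes. Steps between low FPKM values implied a depth of 16.5, 18.6 and 16.5 M fragments in L-OHP replicates 1 to 3 and of 18.4, 15.7 and 16.3 M in L-OHP+FUC replicates 1 to 3. Genes at 1 FPKM or more numbered 10749 ± 55.5 with L-OHP and 10015 ± 174 with L-OHP+FUC (SD, n = 3; exact two-sided permutation p = 0.1, the smallest that 3 against 3 allows). Mitochondrial transcripts held 7.61% ± 1.69 of the summed FPKM with L-OHP and 9.22% ± 0.33 with L-OHP+FUC (SD, n = 3; exact two-sided permutation p = 0.2). Across tested genes, Pearson's r was 0.968 to 0.981 among L-OHP libraries, 0.983 to 0.988 among L-OHP+FUC libraries and 0.950 to 0.965 between the groups, where genes are not independent replicates. The labels do not say that the replicates were separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.

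Macrophages given fucoidan before the drug carried more mRNA of the neutrophil-attracting chemokines Cxcl1, Cxcl2 and Cxcl3 and of the cytokine Il1a, and more mRNA of the antioxidant genes Srxn1 and Hmox1 and of the glycolytic enzyme Eno1. Members past the threshold as higher numbered 13 of 33 in the inflammatory list, 21 of 29 in the NRF2 list and 11 of 24 in the glycolysis list (adjusted p = 0.498, 0.0572 and 0.0697 with an estimated correlation). The macrophages given fucoidan carried less mRNA of the interferon-stimulated genes Stat2 and Xaf1, of Hmgcs1 and Insig1 of cholesterol synthesis and its control, and of Mdm2, a negative regulator of p53. Of 31 interferon-stimulated genes 16 fell and of 24 cholesterol biosynthesis genes 10 fell, and the others did not pass (adjusted p = 0.535 and 0.498 with an estimated correlation). Of 12084 genes tested with limma, 3262 passed an adjusted p of 0.05, of which 927 were higher and 2335 lower in L-OHP+FUC. At 2-fold or more, 57 passed as higher and 366 as lower.

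At 2-fold or more, the excess of lower genes stayed after rescaling or correction. There, 262 of 338 calls were lower after median ratio rescaling, 230 of 304 after quantile normalization and 179 of 273 after the GC and length correction. Over all calls the excess depended on scaling and on base composition, although these steps centre the genes and so favour an even split. Rescaling each library to its median ratio gave 1581 higher and 1680 lower genes, quantile normalization gave 1565 and 1359, and a correction for GC content and transcript length gave 1390 and 1437. Of these, 2068 genes were called both with and without that correction, all with the same sign. The median log2 fold change of all tested genes moved from -0.10 to 0.03 under quantile normalization and to 0.01 under the GC and length correction. The total fell to 1402 without L-OHP replicate 1, to 1224 without L-OHP+FUC replicate 1 and to 1101 without L-OHP+FUC replicate 2, and the higher genes alone to 615 without L-OHP replicate 3. In the authors' deposited table, 1467 genes were marked significant, 164 higher and 1303 lower, a mark given only from 2-fold upwards. At any fold, 2985 genes had a q-value under 0.05 in the authors' deposited table, 1229 higher and 1756 lower. Of the 3262 genes, 2328 also had a q-value under 0.05 in the authors' deposited table, all with the same sign.

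Cxcl2 rose from 8.82 ± 1.94 to 52.1 ± 3.89 FPKM (SD, n = 3; log2 fold change 2.45, SE 0.15, adjusted p = 0.00128). It lies on chromosome 5 at 90903871 to 90905938 of mm10, near Cxcl1 (90891241 to 90893115) and Cxcl3 (90786103 to 90789600), which rose from 0.579 ± 0.0279 to 4.94 ± 0.505 FPKM and from 0.319 ± 0.175 to 5.17 ± 1.27 FPKM (SD, n = 3; limma adjusted p = 0.000936 and 0.00336). Ranks depend on the pseudocount, since with 0.1 in place of 1 the log2 fold change was 3.72 for Cxcl3 and 2.57 for Cxcl2. Fpr1, a receptor for formylated peptides of bacteria and mitochondria on chromosome 17 (17876471 to 17883940), rose from 62.4 ± 8.46 to 280 ± 41.9 FPKM (log2 fold change 2.14, SE 0.15, adjusted p = 0.00200). Slpi, a secreted inhibitor of leukocyte proteases, rose from 24.6 ± 3.25 to 88.3 ± 16.9 FPKM (log2 fold change 1.79, SE 0.16, adjusted p = 0.00339). The others among the 8 highest were Gemin7, Mir142hg and Snord100. Snord100 lies inside Rps12 on the same strand and Mir142hg opposite Mir142b, so reads of these pairs may not be told apart. Gemin7 lost its call without L-OHP+FUC replicate 1 (adjusted p = 0.0785) or replicate 2 (adjusted p = 0.0693), and without a filter on low genes (adjusted p = 0.0630).

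Among the 8 lowest, Ms4a14, a member of the membrane-spanning 4A family on chromosome 19 (11301249 to 11314454), fell from 55.2 ± 11.7 to 7.97 ± 3.69 FPKM (SD, n = 3; log2 fold change -2.71, SE 0.32, adjusted p = 0.00479). The neighbouring genes 9930111J21Rik1 and 9930111J21Rik2 on chromosome 11 fell from 14.8 ± 1.09 to 2.38 ± 1.27 FPKM and from 21.5 ± 1.25 to 2.34 ± 0.762 FPKM (adjusted p = 0.00432 and 0.00128). Both overlap Olfr56 on the opposite strand, and 9930111J21Rik1 also overlaps Psme2b on the same strand. Guca1a, which encodes a guanylate cyclase activator of photoreceptors, was listed at 0 in all 3 L-OHP+FUC libraries against 4.02, 5.16 and 6.30 FPKM in the L-OHP libraries. Evi2 and Mir5125 also fell, but Evi2 overlaps Evi2a and Evi2b and Mir5125 lies inside Srrm2, each on the same strand. The pseudogenes Ifi203-ps and Rpl35a-ps3 can share reads with related copies, and Rpl35a-ps3 lost its call when any library except L-OHP replicate 2 was left out (adjusted p = 0.0632 to 0.0858). After the GC and length correction the log2 fold change of Rpl35a-ps3 went from -2.85 (SE 0.71) to -2.44 (SE 0.74), without a call (adjusted p = 0.0545), and it had none without a filter either (0.0789).

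**Figure D1:**
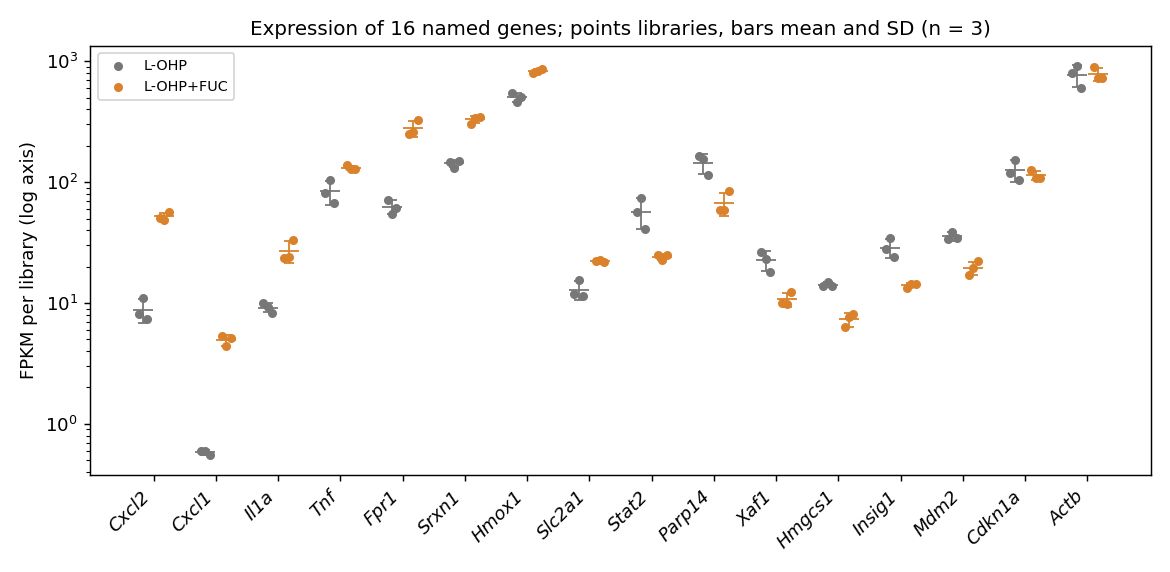
FPKM of 16 named genes in each library on a log axis, with L-OHP in grey and L-OHP+FUC in orange; points are the 3 libraries of a group, and the horizontal and vertical bars are their mean and SD. Cxcl2 stood at 8.82 FPKM with L-OHP and 52.1 FPKM with L-OHP+FUC, whereas Actb stood at 770 and 784 FPKM.

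In the list of inflammatory cytokines and NF-kB targets, 13 of 33 tested members rose, 2 fell and 18 did not pass (20 higher and 3 lower adjusted over the list alone), and the median log2 fold change was 0.55. Beside the 3 Cxcl chemokines, Il1a, an alarm cytokine of the interleukin-1 family, rose from 9.16 ± 0.788 to 26.9 ± 5.54 FPKM (SD, n = 3; log2 fold change 1.44, SE 0.15, adjusted p = 0.00407). Il1b rose from 3.17 ± 1.59 to 7.12 ± 0.747 FPKM (adjusted p = 0.0336) and Tnf from 83.9 ± 18.9 to 131 ± 5.72 FPKM (adjusted p = 0.0270). Both lost their calls without L-OHP replicate 1 (adjusted p = 0.0845 and 0.0812), L-OHP+FUC replicate 1 (0.0963 and 0.0914), replicate 2 (0.0802 and 0.0801) or replicate 3 (0.0837 and 0.0592), and without a filter (0.0871 and 0.0662). Il6 stood at 0.308 ± 0.120 and 1.11 ± 0.606 FPKM (adjusted p = 0.0560) and passed as higher without L-OHP+FUC replicate 2 (0.0461) and after the GC and length correction (0.0172). It also passed with a pseudocount of 0.1 (0.0474), median ratio rescaling (0.0439), quantile normalization (0.0227) or protein-coding genes only (0.0426). Nos2, the inducible nitric oxide synthase, stood at 4.55 ± 2.59 and 4.87 ± 0.828 FPKM (adjusted p = 0.713). The 2 members that fell, named after their values were seen, were Ccl5 (log2 fold change -1.45, adjusted p = 0.0356) and Il12b (-1.41, adjusted p = 0.0246). The list passed limma's camera test with a preset correlation (adjusted p = 3.87e-08) and after the GC and length correction (4.59e-06), but adjusted p = 0.498 with an estimated correlation. The mean deviation of the members from their gene means, in log2 units, was -0.24, 0.05 and -0.59 in L-OHP replicates 1 to 3 and 0.31, 0.14 and 0.34 in the L-OHP+FUC replicates, so that L-OHP replicate 2 stood close to L-OHP+FUC replicate 2.

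Among interferon-stimulated genes, none of 31 tested members rose, 16 fell and 15 did not pass (19 lower adjusted over the list alone), with a median log2 fold change of -0.70. Stat2, a transcription factor of the type I interferon response on chromosome 10 (128270559 to 128292849), fell from 57.0 ± 16.3 to 24.2 ± 1.35 FPKM (SD, n = 3; log2 fold change -1.16, SE 0.20, adjusted p = 0.0111). Xaf1 fell from 22.6 ± 4.22 to 10.7 ± 1.42 FPKM (adjusted p = 0.00883), Parp14 from 144 ± 26.7 to 67.4 ± 14.5 FPKM (adjusted p = 0.0119) and Ifi44 from 23.2 ± 4.51 to 8.18 ± 3.49 FPKM (adjusted p = 0.0132). Ifi44 lost its call without L-OHP+FUC replicate 1 (adjusted p = 0.0515). The mean deviation of the members from their gene means, in log2 units, was 0.51, 0.64 and -0.08 in L-OHP replicates 1 to 3 and -0.35, -0.50 and -0.23 in the L-OHP+FUC replicates, so that L-OHP replicate 3 stood lower than the rest of its group. Camera gave adjusted p = 0.000172 for the list and 4.59e-06 after the GC and length correction, but adjusted p = 0.535 with an estimated correlation. The list did not pass fry in 1 direction (adjusted p = 0.0863).

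Among targets of NRF2, the transcription factor of the antioxidant response, 21 of 29 tested members rose, none fell and 8 did not pass (22 higher adjusted over the list alone), with a median log2 fold change of 0.61. Srxn1, which repairs oxidized peroxiredoxins, rose from 143 ± 10.7 to 330 ± 23.3 FPKM (SD, n = 3; log2 fold change 1.20, SE 0.10, adjusted p = 0.00339). Increases were also measured for the peroxiredoxin Prdx6 (log2 fold change 1.05, adjusted p = 0.00575), the carbonyl reductase Cbr3 (0.91, adjusted p = 0.00480) and the thioredoxin reductase Txnrd1 (0.68, adjusted p = 0.00459). Hmox1, the haem-degrading enzyme, rose from 507 ± 43.3 to 829 ± 33.6 FPKM (log2 fold change 0.71, SE 0.11, adjusted p = 0.00890). Camera gave adjusted p = 1.48e-13 and 1.58e-10 after the GC and length correction, but adjusted p = 0.0572 with an estimated correlation.

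In the glycolysis and hypoxia list, 11 of 24 tested members rose, none fell and 13 did not pass (11 higher adjusted over the list alone), with a median log2 fold change of 0.37. The lactate exporter Slc16a3 rose from 4.36 ± 0.519 to 9.21 ± 0.784 FPKM (SD, n = 3; log2 fold change 0.93, SE 0.11, adjusted p = 0.00464) and the glucose transporter Slc2a1 from 12.9 ± 2.31 to 22.2 ± 0.427 FPKM (log2 fold change 0.75, SE 0.13, adjusted p = 0.0103). The glycolytic enzymes Eno1 (log2 fold change 0.70, adjusted p = 0.00709) and Aldoa (0.66, adjusted p = 0.0104) rose too, Aldoa losing its call without L-OHP+FUC replicate 2 (adjusted p = 0.0524). Gapdh, whose many pseudogenes can take its reads, stood at 5.07, 5.63 and 8.68 FPKM in the L-OHP libraries and at 26.2, 8.95 and 5.70 FPKM in L-OHP+FUC replicates 1 to 3 (log2 fold change 0.74, adjusted p = 0.295). Without L-OHP+FUC replicate 1 its log2 fold change was 0.16. Actb, often used as a reference gene, stood at 770 ± 154 and 784 ± 95.96 FPKM (adjusted p = 0.887). Camera gave adjusted p = 6.49e-06 for the list and 0.000119 after the GC and length correction, but adjusted p = 0.0697 with an estimated correlation.

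In the cholesterol biosynthesis list, none of 24 tested members rose, 10 fell and 14 did not pass (10 lower adjusted over the list alone), with a median log2 fold change of -0.33. Hmgcs1, an early enzyme of the mevalonate pathway on chromosome 13 (119690379 to 119708260), fell from 14.2 ± 0.636 to 7.35 ± 0.966 FPKM (SD, n = 3; log2 fold change -0.87, SE 0.11, adjusted p = 0.00537). Insig1, which holds the sterol sensor in the endoplasmic reticulum, fell from 28.7 ± 5.12 to 13.98 ± 0.517 FPKM (log2 fold change -0.97, SE 0.13, adjusted p = 0.00667). Stard4 and Sc5d also fell (adjusted p = 0.00706 and 0.00798), but the GC and length correction took the log2 fold change of Sc5d from -0.63 (SE 0.09) to -0.35 (SE 0.11), which ended its call (adjusted p = 0.0631). Camera gave adjusted p = 0.00655 and 0.000767 after the GC and length correction, but adjusted p = 0.498 with an estimated correlation. Within the list of LXR targets and lipid handling, 3 of 28 members rose and 4 fell (camera adjusted p = 0.286). The lipid droplet protein Plin2 (log2 fold change 1.11, adjusted p = 0.00842) and Cpt1a, which commits fatty acids to mitochondrial import (0.45, adjusted p = 0.00978), were higher. The cholesterol exporter Abca1 fell from 63.4 ± 4.75 to 39.9 ± 6.23 FPKM (-0.66, adjusted p = 0.0149). Abca1 lost its call without L-OHP+FUC replicate 2 (adjusted p = 0.0584), and after the GC and length correction its log2 fold change was -0.30 (SE 0.08, adjusted p = 0.0438).

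A further 6 lists passed camera as higher, with fewer members past the threshold and all without a call when the correlation was estimated. Extracellular matrix and matrix enzymes held 3 higher and no lower of 21 (adjusted p = 0.000436; adjusted p = 0.447 with an estimated correlation), led by the gelatinase Mmp9 (log2 fold change 1.28, SE 0.15, adjusted p = 0.00436) and the fibronectin receptor subunit Itga5 (log2 fold change 0.79, adjusted p = 0.00433). The mean deviation of the members from their gene means, in log2 units, was -0.22, -0.22 and 0.04 in L-OHP replicates 1 to 3. It was 0.14, 0.15 and 0.12 in the L-OHP+FUC replicates, so that L-OHP replicate 3 stood apart from its group. Lysosome and autophagy genes held 6 higher and 3 lower of 36 (adjusted p = 0.00507; adjusted p = 0.498 with an estimated correlation). Among them the autophagy receptor Sqstm1 rose from 617 ± 96.7 to 1387 ± 66.2 FPKM (log2 fold change 1.18, SE 0.14, adjusted p = 0.00523). Atp6v0d1 rose too (0.62, adjusted p = 0.0144), whereas Mcoln1 (-0.37, adjusted p = 0.0172) and Ulk1 (-0.40, adjusted p = 0.0162) fell. Each of these 3 lost its call without L-OHP+FUC replicate 1 or replicate 2 (adjusted p = 0.0530 to 0.0691). Genes of the ER stress and integrated stress responses held 7 higher and 3 lower of 29 (adjusted p = 0.00507; adjusted p = 0.447 with an estimated correlation). Phgdh and Asns, enzymes of serine and asparagine synthesis, and Shmt2, which converts serine to glycine in mitochondria, rose (log2 fold changes 1.19 for Phgdh, 0.81 for Asns and 0.90 for Shmt2; adjusted p = 0.00811, 0.00339 and 0.00499). The stress-induced transcription factor Ddit3 fell from 70.5 ± 11.3 to 35.0 ± 1.22 FPKM (SD, n = 3; adjusted p = 0.00631), although Ddit3 overlaps Mars1 on the opposite strand.

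Immediate early genes held 7 higher and 1 lower of 21 (adjusted p = 0.00727; adjusted p = 0.289 with an estimated correlation), with the phosphatase Dusp5 higher (log2 fold change 0.82, adjusted p = 0.00479) and the mRNA decay factor Zfp36l1 lower (-1.09, adjusted p = 0.00620). Alternative activation genes held 4 higher and 1 lower of 10 (adjusted p = 0.0354; adjusted p = 0.447 with an estimated correlation), led by the transglutaminase Tgm2 (22.9 ± 1.63 to 47.1 ± 3.45 FPKM, SD, n = 3; adjusted p = 0.00339). Arg1 stayed under the filter with at most 0.514 FPKM in any library. The alternative activation list lost its call without L-OHP replicate 2 (adjusted p = 0.157) or L-OHP+FUC replicate 3 (adjusted p = 0.0537). The mean deviation of its members from their gene means, in log2 units, was -0.136, -0.221 and 0.068 in L-OHP replicates 1 to 3. It was 0.065, 0.054 and 0.170 in the L-OHP+FUC replicates, so the groups overlapped. Neutrophil markers held 2 higher and no lower of 6 tested (adjusted p = 0.0237; adjusted p = 0.362 with an estimated correlation), namely Lcn2 (10.2 ± 2.00 to 26.4 ± 4.69 FPKM, adjusted p = 0.00684) and S100a8 (2.58 ± 0.274 to 4.23 ± 0.496 FPKM, adjusted p = 0.0162). The neutrophil list lost its call without L-OHP replicate 2 (adjusted p = 0.0504), and S100a8 lost its own without L-OHP replicate 1 (adjusted p = 0.0589) or L-OHP+FUC replicate 2 (adjusted p = 0.0651). After the GC and length correction the lysosome (adjusted p = 0.0805), ER stress (0.0773), immediate early (0.237), alternative activation (0.110) and neutrophil (0.102) lists no longer passed, whereas the extracellular matrix list did (0.00437). The median log2 fold change went from 0.29 to 0.19 in the immediate early list, but from 0.13 to 0.13 in the lysosome list and from 0.18 to 0.21 in the ER stress list. It went from 0.22 to 0.28 in the alternative activation list and from 0.36 to 0.56 in the neutrophil list. Camera compares a list with the other tested genes, and the median of all tested genes went from -0.10 to 0.01. The lysosome, ER stress, immediate early and alternative activation medians thus came closer to that of all genes, while the neutrophil median moved further from it. Why these calls ended was not tested. The same 5 lists lost their calls under quantile normalization (adjusted p = 0.313 for lysosome, 0.178 for ER stress, 0.0866 for immediate early, 0.132 for alternative activation and 0.0866 for neutrophils). Their medians were then 0.10, 0.16, 0.30, 0.37 and 0.56, against 0.03 for all tested genes. At a mean of at least 5 FPKM the lysosome (0.0916), ER stress (0.117), immediate early (0.797, median 0.11) and alternative activation (0.679) lists did not pass. Alternative activation also lost its call after median ratio rescaling (0.0601, median 0.34) and, with the median near 0, without a filter (0.163).

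Neither the list for extracellular DNA and NET degradation nor that for efferocytosis and phagocytosis passed camera. Both held higher and lower members, as did all 12084 tested genes (927 higher and 2335 lower). In the list for extracellular DNA and NET degradation, 1 of 13 tested members rose and 4 fell (camera adjusted p = 0.929). The cytosolic DNA sensor Aim2 fell from 13.5 ± 1.69 to 7.003 ± 0.406 FPKM (SD, n = 3; log2 fold change -0.85, SE 0.11, adjusted p = 0.00566) and the nuclease Dnase1 from 1.06 ± 0.136 to 0.411 ± 0.0534 FPKM (adjusted p = 0.0120), although Dnase1 overlaps the opposite-strand gene Trap1. The lysosomal nuclease Dnase2a did not pass (log2 fold change 0.17, SE 0.10, adjusted p = 0.263), and Dnase1l3, with at most 1.60 FPKM in any library, was not tested. Of 32 efferocytosis and phagocytosis genes 1 rose and 5 fell (camera adjusted p = 0.607). Mertk, a receptor for apoptotic cells, fell from 50.5 ± 2.82 to 29.9 ± 0.775 FPKM (log2 fold change -0.74, SE 0.08, adjusted p = 0.00432). Of 15 scavenger receptors 1 fell and none rose (camera adjusted p = 0.286). It was Clec7a (log2 fold change -0.61, adjusted p = 0.0185), which lost its call without L-OHP replicate 1 (adjusted p = 0.0552), L-OHP+FUC replicate 1 (0.0699) or replicate 2 (0.0647). The GC and length correction took it from -0.61 (SE 0.13) to -0.34 (SE 0.10), which ended its call (adjusted p = 0.0526). Msr1, a scavenger receptor that binds sulfated polysaccharides, stood at 35.4 ± 2.30 and 26.5 ± 6.64 FPKM (adjusted p = 0.110), Cd36 at 193 ± 39.5 and 256 ± 26.4 FPKM (adjusted p = 0.101) and Marco at 119 ± 30.8 and 114 ± 14.4 FPKM (adjusted p = 0.936). Msr1 passed as lower without L-OHP+FUC replicate 3 (adjusted p = 0.0340) and Cd36 as higher without L-OHP replicate 3 (0.0420) or with median ratio rescaling (0.0449). After the GC and length correction the log2 fold change of Msr1 went from -0.43 (SE 0.18) to -0.10 (SE 0.11, adjusted p = 0.541), and that of Cd36 from 0.43 (SE 0.17) to 0.75 (SE 0.12, adjusted p = 0.00895).

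Among genes tied to DNA damage and growth, 8 of 25 p53 targets fell and none rose (1 higher and 11 lower adjusted over the list alone; median log2 fold change -0.32). Mdm2 fell from 35.7 ± 2.91 to 19.5 ± 2.49 FPKM (SD, n = 3; log2 fold change -0.84, SE 0.12, adjusted p = 0.00695), while the cell cycle inhibitor Cdkn1a stood at 126 ± 25.2 and 114 ± 9.88 FPKM (adjusted p = 0.566). Camera gave adjusted p = 0.0917 for the p53 list, 0.0161 after the GC and length correction, 0.0437 under quantile normalization, 0.0485 over protein-coding genes only and adjusted p = 0.447 with an estimated correlation. Mki67, a proliferation marker, fell from 3.37 ± 0.495 to 0.474 ± 0.285 FPKM (log2 fold change -1.58, SE 0.17, adjusted p = 0.00432), but was the only G2M gene of 9 tested to pass (camera adjusted p = 0.286), and 1 of 24 S phase genes fell (0.960). That gene, Dut, lost its call when any library except L-OHP replicate 2 was left out (adjusted p = 0.0900 to 0.137). After the GC and length correction its log2 fold change went from -0.38 (SE 0.11) to -0.35 (SE 0.10), with the adjusted p moving from 0.0468 to 0.0516. Dut also lost its call without a filter (adjusted p = 0.124), with median ratio rescaling (0.0801, log2 fold change -0.31) and with quantile normalization (0.343, -0.15). DNA repair held 1 higher and 5 lower of 20 (0.287), with Parp2 lower (-0.72, adjusted p = 0.0125). The DNA repair list passed camera as lower without a filter (adjusted p = 0.0461). Ribosome biogenesis held 6 higher and 6 lower of 30 (0.175), and nuclear subunits of oxidative phosphorylation 7 higher and 1 lower of 30 (0.0643). The oxidative phosphorylation list passed as higher, relative to the other tested genes, with median ratio rescaling (0.0398) and without a filter (0.0159, median -0.02). It also passed so without L-OHP replicate 1 (0.0344) or L-OHP+FUC replicate 3 (0.0403, median -0.04). With an estimated correlation over all libraries, its camera adjusted p was 0.535.

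For surface and secreted proteins of immunity, 3 of 11 genes of class II antigen presentation fell and none rose (camera adjusted p = 0.224). The list passed as lower without L-OHP replicate 3 (0.0196) and after the GC and length correction (0.0420), but adjusted p = 0.689 with an estimated correlation, and 0.513 with an estimated correlation after the GC and length correction. The costimulatory ligand Cd86 fell from 21.2 ± 4.31 to 10.02 ± 1.60 FPKM (SD, n = 3; SE of the log2 fold change 0.18, adjusted p = 0.0117). Complement and coagulation held 1 higher and 1 lower of 21 (camera adjusted p = 0.929), the urokinase receptor Plaur (log2 fold change 0.95, adjusted p = 0.00583) and C3 (-0.71, adjusted p = 0.0363). C3 lost its call without L-OHP replicate 1 (adjusted p = 0.104), L-OHP replicate 2 (0.0711), L-OHP+FUC replicate 1 (0.111) or L-OHP+FUC replicate 2 (0.120), without a filter (0.0907) and, at -0.59, with median ratio rescaling (0.0623). Macrophage markers held 2 higher and 4 lower of 15 (0.821). Among them, Aif1 fell from 77.2 ± 7.21 to 31.6 ± 2.49 FPKM (log2 fold change -1.26, SE 0.11, adjusted p = 0.00339). Osteoclast markers held 2 higher (Mmp9 and Acp5) and 1 lower of 7 (0.224), a list that passed without a filter (0.0437), and no fibroblast or stromal marker of 7 passed (0.320). Fewer than 5 members were tested for the remaining cell types, in which Pf4 and Ppbp of the megakaryocyte list rose, Cd4, Cd79b and the dendritic cell marker Batf3 fell, and the mast cell marker Hdc did not pass (adjusted p = 0.857). Batf3 (adjusted p = 0.0496) lost its call when any library except L-OHP replicate 1 was left out (adjusted p = 0.103 to 0.127), and Cd79b (0.0258) without L-OHP replicate 1 (0.0678), L-OHP replicate 3 (0.0689), L-OHP+FUC replicate 2 (0.0888) or L-OHP+FUC replicate 3 (0.0603). Batf3 also lost it with a pseudocount of 0.1 (adjusted p = 0.0512), without a filter (0.119), with median ratio rescaling (0.0717) and with quantile normalization (0.274). Its log2 fold change was -0.44, and -0.38 and -0.22 after these 2 steps. Cd79b lost its call without a filter (0.0537) and with quantile normalization (0.136), which took it from -0.51 to -0.27.

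With a preset correlation 11 of 26 tested lists passed camera, 9 higher and 2 lower, and none passed with an estimated correlation. The fry test, which asks whether a list's genes move on balance in 1 direction without comparing them with other genes, passed 12 lists, and 25 passed for change in either direction. Of the lists past camera, the interferon (fry adjusted p = 0.0863), matrix (0.0705), ER stress (0.0863) and lysosome (0.124) lists did not pass fry in 1 direction. Without a camera call, p53 targets (0.00596), G2M genes (0.0103), macrophage markers (0.0168) and osteoclast markers (0.0480) did. Median, mean and camera direction differed in sign for ribosome biogenesis, oxidative phosphorylation, extracellular DNA and NET degradation, efferocytosis, scavenger receptors, LXR targets, complement and fibroblasts. None of these 8 passed camera, whereas complement passed fry in 1 direction (adjusted p = 0.0122) and all of them but fibroblasts (0.646) passed fry for change in either direction.

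**Figure D2:**
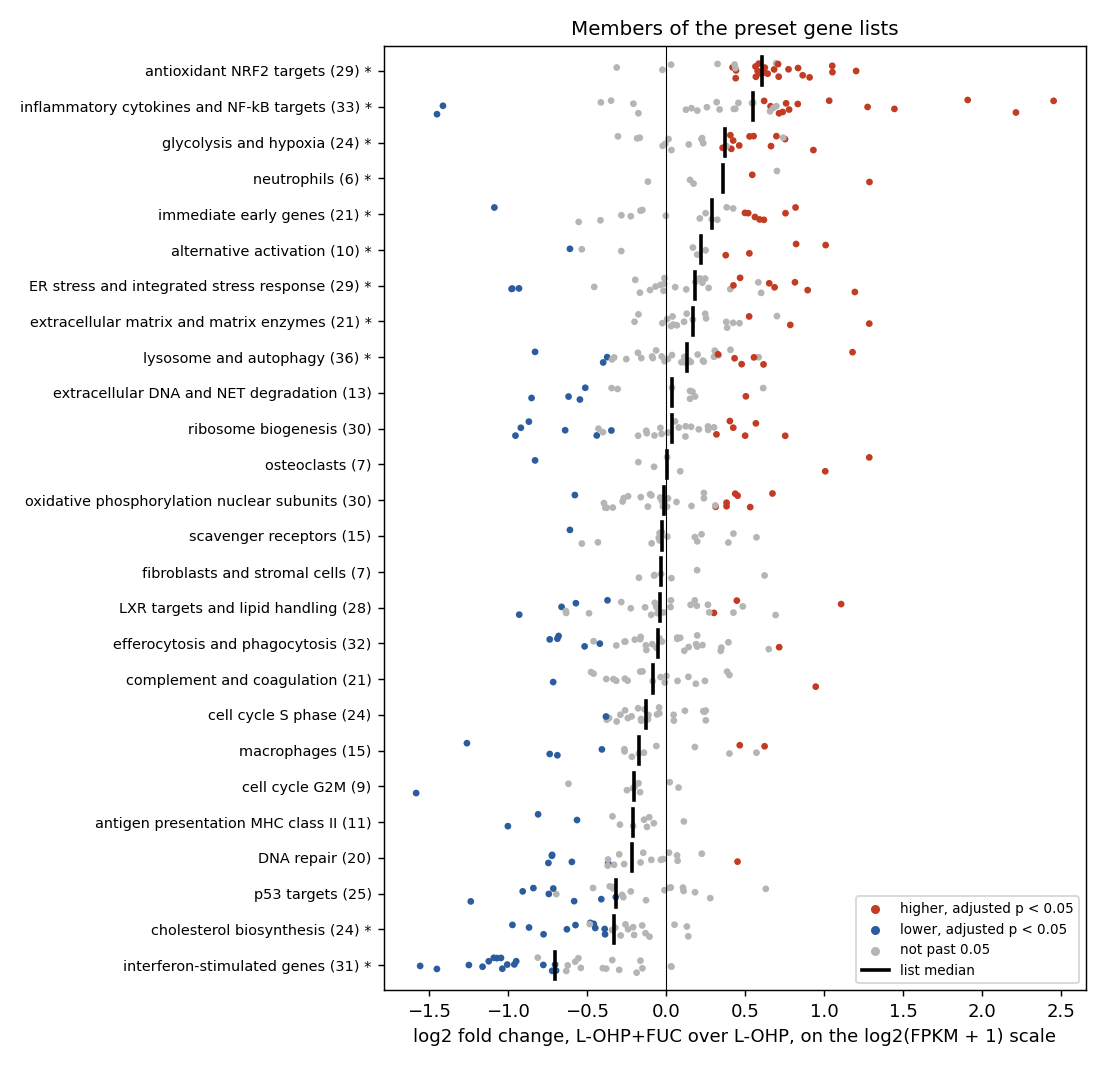
Log2 fold change (L-OHP+FUC over L-OHP, on the log2(FPKM + 1) scale) of each tested member of 26 gene lists, with the number of tested members in parentheses and an asterisk where camera with a preset correlation passed 0.05. Red and blue points passed the adjusted threshold as higher and lower, grey points did not, and black bars are list medians, which run from -0.70 for interferon-stimulated genes to 0.61 for antioxidant NRF2 targets.

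The libraries differed in base composition in a way that followed the groups in part. Over 10176 protein-coding genes the log2 fold change rose with the GC content of the longest transcript (Spearman's rho across genes 0.39, where genes are not independent replicates). In the 10% of genes with the lowest GC content, 334 fell and 17 rose, and in the 10% with the highest, 82 fell and 170 rose. The median log2 deviation of the lowest 10% was 0.18, 0.07 and 0.29 in L-OHP replicates 1 to 3 and -0.31, -0.21 and 0.00 in L-OHP+FUC replicates 1 to 3. Without the steepest library of each group, L-OHP replicate 3 and L-OHP+FUC replicate 1, 367 genes passed, 75 higher and 292 lower, and 12 lists passed. Of 85 genes covered by the naming rule and past the threshold, 48 lost their calls in that fit, which had 4 libraries in place of 6. Among them, Hmox1 had a log2 fold change of 0.75 in that fit against 0.71 over all libraries (adjusted p = 0.0618 without the pair) and Mdm2 -0.78 against -0.84 (0.0551). Tnf had 0.47 against 0.66 (0.132). After the GC and length correction over all 6 libraries, 6 of the 85 genes lost their calls. Hmox1 (0.66, adjusted p = 0.0104), Mdm2 (-0.73, 0.00822) and Tnf (0.64, 0.0296) kept theirs. With all 6 libraries, most of the 85 calls thus did not depend on the GC and length trends. That fit kept every sample, so it cannot show why the 48 calls ended without the pair. Whether the smaller number of samples ended these calls was not tested.

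**Figure D3:**
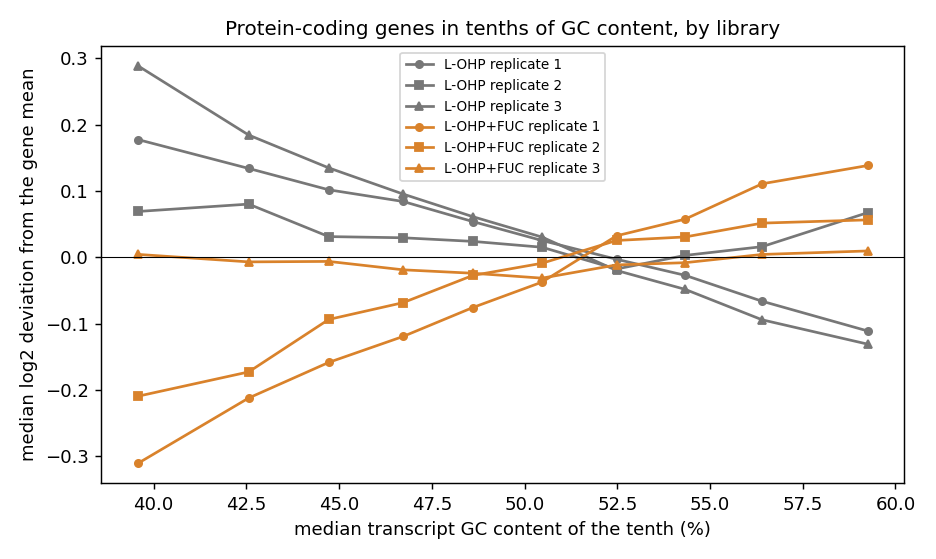
Median log2 deviation from the gene mean (vertical axis) for protein-coding genes in 10 equal classes of GC content, placed at the median GC percentage of each class (horizontal axis), with a line per library, L-OHP in grey and L-OHP+FUC in orange. In the lowest class the libraries ranged from -0.31 in L-OHP+FUC replicate 1 to 0.29 in L-OHP replicate 3, with L-OHP replicate 2 (0.07) and L-OHP+FUC replicate 3 (0.00) close together.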

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

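The correction for GC content and length, its fit with a block, the restriction to protein-coding genes and the fit without the libraries of steepest GC trend were chosen after seeing the data. Of the 3262 genes, none was called in the opposite direction under any alternative. The planned count-based tests were not run, since the table holds no counts. With 3 libraries per group, 1.5-fold changes were recovered for 40.3% of simulated genes and 2-fold changes for 97.0%. The simulated noise was independent between genes, so recovery in the real data may differ. Where no other cause is given, the cause was not tested.

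Fewer genes passed without a filter (2092, with 564 higher and 1528 lower), where 24822 were tested, and at a mean of at least 5 FPKM (1720, 966 lower, 6 lists), where 5917 were. Median ratio rescaling gave 1581 higher genes. Quantile normalization gave 1565 higher and 1359 lower genes and 7 lists. The GC and length correction gave 1437 lower genes. Without the libraries of steepest trend, 367 genes passed, 75 higher and 292 lower, with fewer samples. At a threshold of 0.1, 1436 genes were higher, at 0.01 637 passed (165 higher, 472 lower), and at a fold of at least 2 423 did (57 higher, 366 lower). With an estimated correlation, 0 lists passed. The 6 lists of inflammatory, interferon, cholesterol, NRF2, glycolysis and matrix genes passed under all 17 alternatives that kept the preset correlation.

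Leaving out a library gave 1101 to 3377 genes, 266 to 1121 of them higher and 835 to 2256 lower, and 9 to 12 lists. The counts fell by over 1.5 times without L-OHP replicate 1 (1402), L-OHP+FUC replicate 1 (1224) or L-OHP+FUC replicate 2 (1101), and that of higher genes also without L-OHP replicate 3 (615), with fewer samples.

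Deviations of same-numbered libraries correlated at -0.04, -0.07 and 0.08, which gave no sign of pairing by replicate number. These values cannot exclude a shared culture or animal, on which the labels are silent, and differently numbered libraries were not compared. With the replicate block 2316 genes passed, 554 higher and 1762 lower, and 11 lists. With the replicate block and the GC and length correction, 1460 genes passed, 655 higher and 805 lower, and 8 lists.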

Other observations

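The pathway test, the description of gene classes, the rescaling tests of the excess of lower genes, the use of left-out libraries to bound its share and the test for neutrophils were chosen only after results had been seen, and the genes named in this part were chosen after their values were seen. In the KEGG annotation of the authors' deposited table, 86 of 272 pathways passed camera with a preset correlation, 43 of them also after the GC and length correction (42 higher and 1 lower), and 0 with an estimated correlation. Higher is relative to the other tested genes, and the median log2 fold change of all tested genes was -0.10. The C-type lectin receptor pathway thus passed as higher (camera adjusted p = 0.0496) with a median of -0.0017. Glutathione metabolism and ferroptosis had the smallest p (adjusted p = 0.000166 for each; 0.313 with an estimated correlation). Glutathione metabolism held 14 higher and 1 lower of 39 genes, and included glutathione reductase Gsr (log2 fold change 0.83, SE 0.12), the transferase Gsta3 (0.86, SE 0.12) and glutathione synthetase Gss (0.71, SE 0.13). The ferroptosis pathway, iron-dependent death by lipid peroxidation, held 14 higher and 2 lower of 36, among them the zinc and iron importer Slc39a14 (0.60, SE 0.08), the lipid peroxide reductase Gpx4 (0.48, SE 0.11) and, lower, the polyamine acetyltransferase Sat1 (-0.93, SE 0.11). The pentose phosphate pathway, which makes NADPH, held 8 higher and 1 lower of 22, with Pgd (0.77, SE 0.10), G6pdx (0.60, SE 0.10) and Tkt (0.57, SE 0.09) higher. Against this direction, the prostaglandin D synthase Hpgds of the glutathione pathway fell (-1.82, SE 0.24).

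Calls among long non-coding, small nucleolar RNA and zinc finger genes were counted without an enrichment test. Of 574 tested long non-coding genes 246 fell and 7 rose, against 1830 lower and 885 higher of 10176 protein-coding genes, and of 75 small nucleolar RNA genes 33 fell and 1 rose. The median log2 fold change of the small nucleolar RNA genes was -0.70 before and -0.07 after the GC and length correction, and that of the long non-coding genes -0.42 and -0.25. The correction was fitted with the short small nucleolar RNA genes included, so their change may be built in and shows no cause. Of 251 genes named Zfp with a number, 79 fell and 5 rose, and after the GC and length correction 42 fell and 7 rose. After that correction the median deviation of long non-coding genes minus that of protein-coding genes was 0.11, 0.13 and 0.15 in the L-OHP replicates and -0.17, -0.16 and -0.12 in the L-OHP+FUC replicates, on the log2 scale. Only 2 genes were listed at 0 in every library of a group and at 1 FPKM or more in every library of the other, Guca1a at 0 with L-OHP+FUC and Gm50461 at 0 with L-OHP. Other splits of the 6 libraries into 3 and 3 each gave 0 or 1 such gene, so little rests on a count of 2.

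More genes were lower than higher with fucoidan, 71.6% of all calls and 86.5% of the calls of 2-fold or more, and the GC and length trends took away part of this excess. After their removal 50.8% of all calls were lower, an outcome that centring favours, but 65.6% of the calls of 2-fold or more, and 64.1% to 71.3% when each library was left out, which argues against the trends as the whole cause for those larger calls. Loss of RNA from annotated non-coding genes alone is argued against as the whole cause only for the calls of 2-fold or more, of which 73.4% were lower among protein-coding genes tested alone after median ratio rescaling (at least 68.5% with a library left out), whereas 52.8% of all their calls were lower then. Scaling to a fixed read total is argued against as the whole cause only for the calls of 2-fold or more, of which 77.5% were lower after median ratio rescaling (72.4% to 81.4%) and 75.7% after quantile normalization, whereas 51.5% and 46.5% of all calls were lower then. Loss of unspliced RNA stays open, since it was not measured and would lower protein-coding genes too, so that the 67.1% of their calls that were lower without rescaling, a share first set to count against it, does not, and so do a combination of these trends, polysaccharide carried into the library reactions, and a lower output of part of the transcriptome after fucoidan.

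The shifts of 5 lists were set against the same GC and length trends with random lists matched on GC content, length and level. The median of the interferon-stimulated genes lay at percentile 0 of 10000 such lists, that of cholesterol biosynthesis at percentile 0.33, and those of the inflammatory, NRF2 and glycolysis lists at percentile 100, so these trends do not account for the 5 shifts as a whole. A candidate explanation is that fucoidan itself, or a contaminant of the preparation such as bacterial products, engaged receptors that raise NF-kB and NRF2 targets. It was not tested, because no sample with fucoidan alone was analysed here. Whether the same signals could also lower the interferon-stimulated genes, or Ccl5 and Il12b in the inflammatory list, was not tested. Lower sensing of drug-damaged DNA or RNA in the cells could lower the interferon-stimulated genes and was not tested either. All 5 lists passed camera under every alternative with a preset correlation, but none with an estimated correlation (adjusted p = 0.535 for interferon-stimulated genes, 0.498 for the cholesterol and inflammatory lists, 0.0572 for NRF2 targets and 0.0697 for glycolysis). Other lists also lay near the ends of their matched random lists. These were p53 targets (percentile 0.28), macrophage markers (1.94), extracellular matrix (97.85), alternative activation (97.93) and immediate early genes (99.53). The lysosome (87.63) and ER stress (93.94) lists lay further inside.

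Of 6 tested neutrophil markers 2 passed as higher, Lcn2 and S100a8, and the list median lay at percentile 99.87 of matched random lists, which argues against the GC and length trends as its cause. The list's camera call was lost with an estimated correlation (adjusted p = 0.362), under quantile normalization (0.0866) and after the GC and length correction (0.102), where the list median went from 0.36 to 0.56, the log2 fold change of Lcn2 from 1.29 (SE 0.18) to 1.23 (SE 0.18) and that of S100a8 from 0.54 (SE 0.11) to 0.96 (SE 0.10), and why the call ended was not tested. A large share of neutrophils in the fucoidan cultures was argued against by their abundant transcripts S100a8, S100a9, Ngp, Camp, Ltf and Retnlg, whose median was at most 0.335 FPKM in any L-OHP+FUC library, while Lcn2 averaged 26.4 FPKM. That test compared no groups, and S100a8, one of the 6, rose from 2.58 to 4.23 FPKM. A small rise in the share of neutrophils is thus not excluded. Of the 16 genes in that list, 6 were expressed enough in these cultures to be tested, and Camp and Mmp8 are also in other lists.

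The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split gave 3262 genes and the highest other split 2, and for lists the real split gave 11 and the highest other 9. In each case 1 of the 10 splits, the real one, gave as many. Each other split sets 2 libraries of a group and 1 of the other against the rest, so it still holds part of the difference between the groups. The rest of that difference enters the spread within each set, which lowers the number of genes called. The gene counts of the other splits were thus bound to be low, and no conclusion is drawn from their gap to 3262. For lists, the other splits passed 3 to 9 with a preset correlation, and why so many passed was not tested.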
